A study of Mus musculus with 9 samples.

How the data were processed

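RNA was measured in 9 libraries from the hypothalamus of CD-1 mice, an outbred strain, at embryonic day 12.5. Per the labels' protocols, coronal slices were cut on a vibratome, 3 zones were microdissected, and total RNA was made into mRNA libraries read as 100 bp pairs on an Illumina instrument. The groups were the ventricular zone, the medial mantle zone and the lateral mantle zone, with 3 libraries each, numbered 1 to 3 in the labels. The labels do not say whether the libraries of a zone came from separate embryos or litters. P-values therefore measure only the spread between these libraries, part of which may be technical.

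The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 per gene and library. The submitters' processing notes name Bowtie2 2.1.0 and the mm10 genome build, and the program that estimated the FPKM values is not given in the sources used here. The table held 38370 rows. 42 identical rows and 133 further rows with a repeated symbol were removed, keeping the row with the highest mean, which left 38195 symbols, of which 34293 matched the reference names. All columns of values were mapped to a library. Coordinates are gene spans of GENCODE release M21 on GRCm38, the assembly called mm10.

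FPKM values are not counts, so no count test was used. Values were analysed as log2(FPKM + 1), which understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 14004 in all, and 24191 were not. limma 3.58.1 in R 4.3.3 fitted 1 mean per zone to all 9 libraries, with empirical Bayes moderation and an intensity trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. A gene was called enriched in a zone when it passed the threshold against each of the other zones with a log2 difference of at least 1 in both.

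The tests, the rule for naming genes, 29 gene lists and the alternative settings were fixed before the data were examined. The rule took, per comparison, the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold, without overlap between libraries and with a mean of at least 5 FPKM in the higher zone, skipping predicted genes. It also took up to 4 members of each list that passed, by size of change, and up to 2 that did not, by mean level, 10 enriched genes per zone, and Cenpj. The 26 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The lists for the choroid plexus, the pituitary primordium and Cenpj alone had too few tested members. 6 list symbols (Ca9, Cdt1, Gins2, Hbb-bs, Hbb-bt and Tubb3) were not analysed here, and results for some single genes are not reported here.

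Depth was estimated from the low values, because a gene's FPKM moves in steps of 1 fragment. In genes with 1 annotated transcript of at least 1500 bp, the most frequent low value times the length was taken as that step. Between 68.3% and 73.8% of low values fell within 0.1 of a whole number of steps, against 20% for evenly spread values. The step was set at the peak of these same values, so values near 1 step match largely by construction. That peak held 127 to 158 of the 368 to 407 low values of a library, so 20% is too low a baseline. This gives relative depth and not exact counts. Single genes at exactly 0 in 1 library while the other 8 held at least 10 FPKM numbered 27 in ventricular zone replicate 3, 15 in medial mantle zone replicate 3, 1 in medial mantle zone replicate 1 and 0 in the other libraries. 9 of the 15 lay within 1 stretch of chromosome 19 (positions 4035407 to 4195420), which makes a 0 a possible failed estimate. Genes with a 0 are therefore given library by library and described as listed at 0.

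The fit was tested on simulated values for the 14004 genes, with 200 genes changed and 20 runs per comparison. With equal noise in all libraries, 4.12% to 4.95% of calls were false across the 3 comparisons. With each library's own noise, false calls made up 10.6% for the ventricular against the medial mantle zone, 4.58% for the ventricular against the lateral mantle zone and 1.33% for the medial against the lateral mantle zone. The adjusted p-values of the first comparison are therefore too small when library noise differs. In that setting the fit recovered 22.5%, 21.4% and 17.9% of genes changed by 1 on the log2 scale, in the same order of comparisons. It recovered 67.4%, 65.0% and 63.5% of genes changed by 2. A limit of 10% on false calls had been set for this test, and the first comparison exceeded it. The equal-noise runs were added afterwards to separate a fault in the fit from unequal noise.

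Alternatives covered the pseudocount, the filter, quantile and trimmed mean scaling, the intensity trend, array weights, the zones in the fit, a replicate block and leaving out each library. Leaving out the 2 shallow libraries together was added after the data were seen. Python 3.11.15, pandas 2.3.3 and minimap2 2.31 were used for the table, the figures and the alignment of transcripts.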

Results

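Gene expression was measured in 3 zones of the embryonic mouse hypothalamus, in 3 libraries each. The ventricular zone lines the ventricle and holds dividing progenitors, and the medial and lateral mantle zones hold neurons that have left it. The study's design states a search for genes specific to a region, and its title names Cenpj. The deposited values were FPKM, and the fold changes given are on the log2(FPKM + 1) scale from limma.

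The implied depth was 4413462 to 8807552 fragments in 7 libraries. It was 261258 in ventricular zone replicate 3 and 537241 in medial mantle zone replicate 3, or 24.7-fold and 12-fold below the median library. A single fragment on a 2 kb gene was worth 1.91 and 0.931 FPKM in these shallow libraries. The root mean square deviation from the zone mean was 0.755 on the log2 scale in ventricular zone replicate 3 and 0.552 in medial mantle zone replicate 3. It was 0.269 to 0.532 in the other libraries, with the highest of these in ventricular zone replicate 2.

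**Figure D1:**
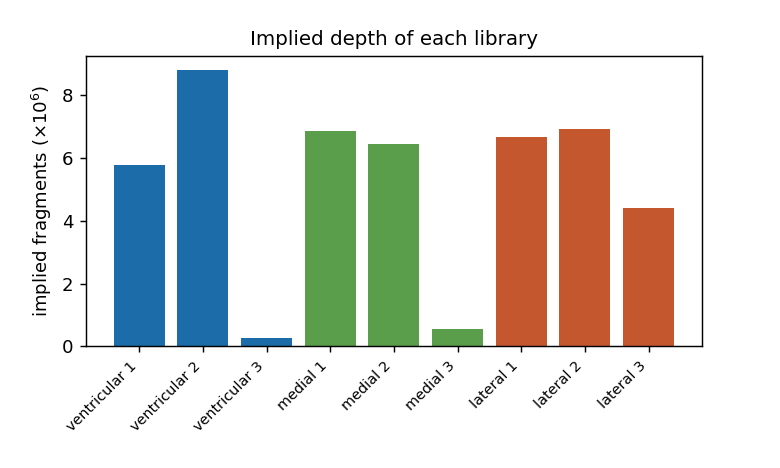
Implied number of fragments (bars, y axis, in units of 10 to the power of 6) for each of the 9 libraries (x axis, coloured by zone). Ventricular zone replicate 3 (261258 fragments) and medial mantle zone replicate 3 (537241 fragments) lie far below the others.

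Cenpj encodes a centriolar protein needed for centriole assembly, and lies on chromosome 14 of GRCm38 from 56526761 to 56575425 on the minus strand. It was present in every library. Its level was 6.03 ± 1.18 FPKM (SD, n = 3) in the ventricular zone, 3.30 ± 0.357 in the medial mantle zone and 1.65 ± 0.266 in the lateral mantle zone. The ventricular zone exceeded the lateral mantle zone by 1.40 ± 0.26 (SE; limma adjusted p = 0.0082), with all 3 libraries of the one above all 3 of the other. The differences between the ventricular and medial mantle zones (0.70 ± 0.26, adjusted p = 0.393) and between the medial and lateral mantle zones (0.70 ± 0.26, adjusted p = 0.174) did not pass. Over the alternative settings the adjusted p ran from 7.8e-05 to 0.0461 for the first, from 0.0171 to 0.702 for the second and from 0.00673 to 0.407 for the third, and the latter 2 passed with array weights. With these weights, mixed splits of the medial and lateral libraries called up to 4409 genes, above the 3700 of the real one.

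**Figure D2:**
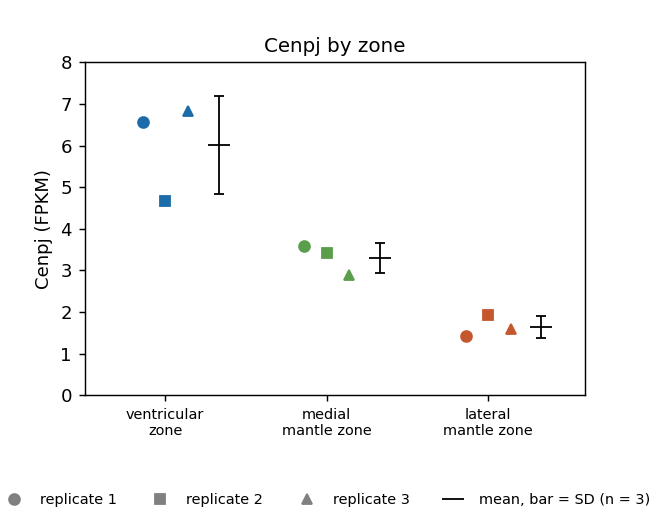
Cenpj in FPKM (y axis) by zone (x axis); each marker is a library and the dash with its bar is the mean and SD (n = 3). Ventricular libraries lie between 4.67 and 6.83 FPKM and lateral ones between 1.41 and 1.94.

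Between the ventricular and lateral mantle zones, genes of dividing progenitors were higher in the ventricular zone and genes of differentiated neurons were higher in the lateral mantle zone. These group differences passed by camera at the preset correlation, but with an estimated correlation no list passed in this comparison (adjusted p = 0.207 for mitosis, 0.129 for radial glia, 0.243 for G1/S and 0.243 for pan-neuronal genes). All 24 measured genes of mitosis and the G2/M phase were higher in the ventricular zone, with a median log2 difference of 3.30. Of 24 radial glia and progenitor genes, 19 were higher, with a median of 2.93, and 20 of 22 genes of DNA replication and G1/S were higher, with a median of 1.99. Of 23 pan-neuronal genes, 19 were lower, with a median of -1.59. In total 2750 of 14004 genes passed, 1500 higher and 1250 lower in the ventricular zone, and 1125 and 966 of these differed at least 2-fold. The larger side depended on the scaling and the libraries, with 1340 higher and 1492 lower with trimmed mean scaling, 1505 and 1534 with quantile normalization, 1955 and 2003 without ventricular zone replicate 2, and 677 and 282 without lateral mantle zone replicate 1.

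Cyclin B1 (Ccnb1), which drives entry into mitosis, was 65.1 ± 49.4 FPKM in the ventricular and 1.18 ± 0.813 in the lateral mantle zone (SD, n = 3; log2 difference 4.72 ± 0.53, limma adjusted p = 0.00086). Top2a, a topoisomerase of dividing cells, was 95.1 ± 67.8 against 2.58 ± 1.69 FPKM. Among progenitor genes, Fabp7, a fatty acid binding protein of radial glia, was 272 ± 102 against 11.6 ± 3.82 FPKM, and the transcription factor Sox9 was 41.7 ± 27.3 against 0.596 ± 0.301 FPKM. Cdh2, the adhesion molecule N-cadherin, did not pass, at 78.4 ± 11.5 against 80.7 ± 7.84 FPKM. Mcm2 and E2f1, from the list of DNA replication and G1/S, had log2 differences of 3.40 ± 0.38 and 3.79 ± 0.42. Counted over the list alone, 24 mitosis, 19 radial glia and 21 G1/S genes were higher (adjusted over the list alone). By camera these lists were higher with adjusted p = 1.54e-19, 6.56e-15 and 7.47e-13.

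Genes of neurogenic commitment followed the same direction, with 15 of 20 higher in the ventricular zone (16 adjusted over the list alone) and a median of 2.27. Mfng, a glycosyltransferase acting on Notch receptors, was 114 ± 31.6 against 2.07 ± 0.867 FPKM, with a log2 difference of 5.23 ± 0.28 (limma adjusted p = 5.18e-05). Nhlh1, a transcription factor of young neurons, was 46.3 ± 23.7 against 0.462 ± 0.391 FPKM. Sox4 and Sox11 did not pass, with Sox4 at 199 ± 21.2 against 160 ± 25.4 FPKM. Signalling lists were also higher: 12 of 16 Notch, 11 of 13 Hedgehog and 10 of 18 Wnt genes passed (13, 11 and 14 adjusted over the list alone, with 1 Notch gene lower in that count). Smo, the Hedgehog signal transducer, was 46.1 ± 19.4 against 4.97 ± 1.14 FPKM, and the ligand Wnt7b was 113 ± 62.2 against 3.22 ± 1.88 FPKM. The Notch list shares Dll1, Dll3 and Mfng with the neurogenic list. It shares Hes1, Hes5, Notch1 and Notch2 with the radial glia list, so these lists are not separate evidence. The camera adjusted p was 2.58e-11 for neurogenic genes, 6.65e-10 for Notch, 1.23e-07 for Hedgehog and 8.36e-08 for Wnt. The estimated correlation gave adjusted p = 0.129 for each of the neurogenic, Notch, Hedgehog and Wnt lists, none of which passed.

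Of 24 centriole and centrosome genes, 10 were higher in the ventricular zone (12 adjusted over the list alone), with a median of 0.89. Cenpj was among them, as were Aspm, a spindle pole protein (8.31 ± 4.71 against 0.316 ± 0.195 FPKM), and Stil, a centriole duplication factor (8.49 ± 7.04 against 0.229 ± 0.034). Odf2 and Cdk5rap2 did not pass, at 55.1 ± 11 against 47.3 ± 6.23 and 46.6 ± 3.20 against 46.9 ± 5.35 FPKM. The camera adjusted p was 0.000415, and 0.353 with an estimated correlation. Primary cilium genes showed no common direction, with 1 higher (Mks1), 1 lower (Kif3a) and 22 not past the threshold, and 0 adjusted over the list alone. Their camera adjusted p was 0.957. Without lateral mantle zone replicate 1, neither Mks1 nor Kif3a passed (adjusted p = 0.103 and 0.15), and each was also lost without any of 6 other single libraries.

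Genes lower in the ventricular than in the lateral mantle zone included the microtubule protein Mapt (74.3 ± 81.5 against 322 ± 36 FPKM) and the granin Scg2 (4.86 ± 2.33 against 24.2 ± 1.53 FPKM). Mapt did not pass without ventricular zone replicate 1 (adjusted p = 0.066) or lateral mantle zone replicate 1, 2 or 3 (0.0682, 0.0728 and 0.0555). The pan-neuronal list had a camera adjusted p of 3.81e-10, and 0.243 with an estimated correlation (20 lower adjusted over the list alone). Elavl4 did not pass, at 70.0 ± 2.98 against 65.8 ± 11.9 FPKM. Of 23 neuropeptide and feeding circuit genes, 9 were lower (11 adjusted over the list alone), with a camera adjusted p of 1.71e-06, and 0.16 with an estimated correlation. The vasopressin gene Avp, on chromosome 2 from 130580620 to 130582554, was 210, 104 and 63.0 FPKM in the lateral libraries and 0.399 in ventricular zone replicate 1, and was listed at 0 in the other ventricular and in all medial libraries. Trh, for thyrotropin-releasing hormone, was 36.5, 19.7 and 58.5 FPKM in the lateral libraries, and 0.266 and 0.785 in ventricular replicates 1 and 2, with replicate 3 listed at 0. Pmch, for melanin-concentrating hormone, was 21.2, 57.3 and 56.1 FPKM in the lateral libraries and 2.58 in ventricular replicate 2, with the others listed at 0. Of 23 lateral hypothalamic and diencephalic markers, 5 were lower and 1 higher, with the same numbers adjusted over the list alone. The camera adjusted p was 0.0324, and 0.353 with an estimated correlation. This list did not pass without ventricular zone replicate 3 (adjusted p = 0.103) or lateral mantle zone replicate 2 (0.0676).

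The strongest single gene was Dbx1, a progenitor transcription factor on chromosome 7 from 49631499 to 49636849. It was 124, 74.0 and 181 FPKM in the ventricular libraries, 0.0694 and 0.109 in lateral replicates 2 and 3, and listed at 0 in lateral replicate 1. The growth factor receptor Fgfr3 was 146 ± 71.5 against 1.93 ± 0.875 FPKM, and Phgdh, an enzyme of serine synthesis, was 71.1 ± 28.3 against 1.21 ± 0.421. Olig2 was 42.8 ± 6.04 against 1.10 ± 0.682 FPKM, and 2 of 7 genes of the oligodendrocyte precursor list were higher (3 adjusted over the list alone; camera adjusted p = 0.0541). Of 14 hypoxia and glycolysis genes 4 were higher (6 higher and 1 lower adjusted over the list alone), among them Ldha at 180 ± 114 against 37.1 ± 6.71 FPKM. That list's camera adjusted p was 0.038, and 0.399 with an estimated correlation. It did not pass without ventricular zone replicate 3 (adjusted p = 0.0661) or lateral mantle zone replicate 3 (0.0751). The oligodendrocyte precursor list passed without ventricular replicate 3, medial replicate 1 or 2 or lateral replicate 1 (adjusted p = 0.0335, 0.0444, 0.0399 and 0.0341).

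Markers of other cell types also differed between these zones. Of 10 erythroid genes, 6 were higher in the ventricular zone (6 adjusted over the list alone; camera adjusted p = 4.7e-05, and 0.199 with an estimated correlation). The embryonic globin Hbb-y was 1065 ± 13.2 FPKM in the ventricular, 1139 ± 286 in the medial and 160 ± 102 in the lateral mantle zone. The adult globin Hbb-b1 did not pass, at 129 ± 36.6, 133 ± 37.5 and 104 ± 25.7 FPKM. The adult alpha globin Hba-a1 was 681 ± 57.7, 654 ± 233 and 202 ± 49.1 FPKM. Summed adult alpha globin differed between the lateral and the other 6 libraries by -1.74 on the log2 scale (exact permutation test, two-sided, p = 0.0119; adjusted p = 0.0179). Hba-a1 and these sums were chosen after their values were seen. The log2 ratio of embryonic to adult beta globin was 2.46 ± 0.224 in the ventricular, 2.34 ± 0.141 in the medial and -0.03 ± 1.17 in the lateral mantle zone. Its difference between the lateral and the other 6 libraries was -2.43 (exact permutation test, two-sided, p = 0.0119, the smallest that 84 splits can give; adjusted p = 0.0179 over 6 such measures). Of 11 microglia and macrophage genes, all 11 had lower means in the ventricular zone and 2 passed, Csf1r and C1qa (2 adjusted over the list alone). C1qa was 4.07 ± 0.71 against 8.95 ± 1.17 FPKM. Neither gene passed without ventricular replicate 1 (adjusted p = 0.0542 and 0.0897) or lateral replicate 1 (0.0898 and 0.12), 2 (0.066 and 0.0737) or 3 (0.0861 and 0.0988), nor C1qa without medial replicate 1 (0.0514). The list's camera adjusted p was 0.00417, and 0.366 with an estimated correlation.

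**Figure D3:**
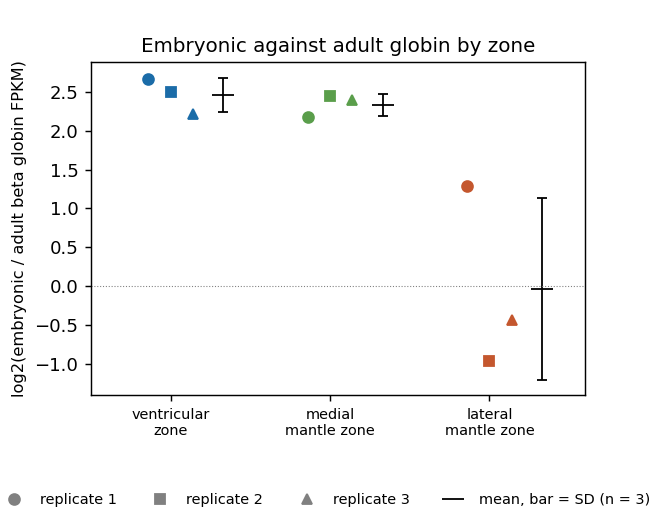
Log2 ratio of the summed FPKM of Hbb-y, Hbb-bh1 and Hba-x to that of Hbb-b1 and Hbb-b2 (y axis) by zone (x axis); markers are libraries, and the dash with its bar is the mean and SD (n = 3). The 6 ventricular and medial libraries lie between 2.18 and 2.66 and the lateral ones between -0.96 and 1.28.

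The 10 remaining lists did not pass by camera between the ventricular and lateral mantle zones. GABAergic genes went both ways, with 3 higher and 4 lower of 16, and the same numbers adjusted over the list alone (adjusted p = 0.288). The adjusted p was 0.957 for glutamatergic genes, 0.853 for medial hypothalamic transcription factors, 0.814 for axon guidance, 0.288 for endothelium, 0.771 for pericytes and 0.643 for meninges. It was 0.771 for cranial ganglia, 0.229 for telencephalon and thalamus, and 0.103 for immediate early genes. Immediate early genes passed without ventricular replicate 1 or lateral replicate 1 (adjusted p = 0.028 and 0.0341), and endothelium without lateral replicate 2 (0.0389). The median and mean differed in sign for medial transcription factors (-0.04 and 0.35), axon guidance (-0.19 and 0.21), pericytes (-0.22 and 0.33) and meninges (-0.26 and 0.50), and the cilium list had a median of 0.05 with a camera direction of down. Within the axon guidance list 6 genes were higher, among them Robo3 (52.4 ± 27.7 against 1.20 ± 0.336 FPKM), and 5 were lower, among them Robo2 (10.4 ± 7.19 against 52.8 ± 37.7 FPKM), with 8 and 6 adjusted over the list alone. Robo2 did not pass without ventricular replicate 1 or 3 (adjusted p = 0.0773 and 0.0574) or lateral replicate 1 or 2 (0.0666 and 0.083).

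In 45.1% of genes the libraries of these zones did not overlap, against 10% by chance. The count of 2750 was 959, 1021 and 1250 without lateral mantle zone replicate 1, 2 or 3 and 1199 without ventricular zone replicate 1. It was 1684 with only these zones in the fit.

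Between the medial and lateral mantle zones, progenitor and proliferation genes were higher medially, and genes of the GABAergic lineage were higher medially as a list (camera adjusted p = 3e-05). With an estimated correlation no list passed in this comparison (adjusted p = 0.0888 for radial glia, 0.142 for mitosis, 0.209 for G1/S and 0.0888 for GABAergic genes). Of 24 mitosis genes 23 were higher (24 adjusted over the list alone), with a median of 2.66, and 20 of 24 radial glia genes were higher (21 adjusted over the list alone), with a median of 2.58. Of 16 GABAergic genes, 6 were higher and 10 did not pass (6 adjusted over the list alone). Of 23 neuropeptide genes, 6 were lower medially (10 adjusted over the list alone). In total 577 genes passed, 501 higher and 76 lower in the medial zone, of which 450 and 72 differed at least 2-fold. The share higher was 86.8% with the deposited scaling and 66.6% after quantile normalization.

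Sox2, a transcription factor of neural progenitors on chromosome 3 from 34650405 to 34652461, was 111 ± 5.10 FPKM in the medial and 8.42 ± 7.58 in the lateral mantle zone (SD, n = 3; log2 difference 3.87 ± 0.53, limma adjusted p = 0.00484). Fabp7 was 201 ± 45.7 against 11.6 ± 3.82 FPKM, and the mitotic gene Ube2c was 53.8 ± 22.8 against 3.64 ± 1.41. By camera, the adjusted p was 6.84e-23 for mitosis and 3.19e-21 for radial glia. Of 22 G1/S genes, 9 were higher (18 adjusted over the list alone), among them Rrm2 at 29.7 ± 12.3 against 2.70 ± 0.705 FPKM. Of 20 neurogenic genes, 10 were higher (17 adjusted over the list alone), among them Dll3, a Notch ligand, at 39.3 ± 12.3 against 3.36 ± 2.51 FPKM. The camera adjusted p was 1.36e-12 for G1/S and 1.48e-12 for the neurogenic list, the latter with adjusted p = 0.0888 with an estimated correlation. The Notch list had 11 of 16 genes higher, the Wnt list 8 of 18 and the Hedgehog list 4 of 13 (12, 10 and 10 adjusted over the list alone). Their camera adjusted p was 1.11e-11, 3.74e-07 and 3.38e-06, and 0.0888, 0.0888 and 0.115 with an estimated correlation. Centriole genes had 2 of 24 higher, Aspm and Spice1 (3 adjusted over the list alone), with a camera adjusted p of 0.000159, and 0.3 with an estimated correlation. Neither passed without lateral mantle zone replicate 2 (adjusted p = 0.185 and 0.137), and each was also lost without several other single libraries.

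Among GABAergic genes, the transcription factor Dlx2 was 80.8 ± 4.56 FPKM in the medial and 19.2 ± 1.95 in the lateral mantle zone, and Lhx6 was 13.1 ± 1.17 against 1.22 ± 0.562. Isl1 did not pass, at 88.4 ± 29.5 against 45.5 ± 2.36 FPKM. Of 20 medial hypothalamic transcription factors, Nkx2-2 (52.4 ± 2.85 against 3.93 ± 1.75 FPKM) and Vax1 (96.0 ± 8.95 against 9.11 ± 11.2 FPKM) were higher, and 8 were higher adjusted over the list alone. Vax1 did not pass without medial replicate 2 or 3 (adjusted p = 0.0568 and 0.0617) or lateral replicate 1 (0.0658), and Isl1 passed without ventricular replicate 3 (0.0445). That list had a camera adjusted p of 0.000129, and 0.154 with an estimated correlation.

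Of the genes lower in the medial zone, Avp was the strongest. Trh was 6.24, 8.01 and 12.8 FPKM in the medial libraries against 36.5, 19.7 and 58.5 laterally. Ghrh, for growth hormone-releasing hormone, was 1.25 and 0.894 FPKM in medial replicates 1 and 2 and listed at 0 in replicate 3, against 13.6, 5.62 and 7.66 laterally. Trh did not pass without ventricular replicate 1, any medial replicate or lateral replicate 1 or 3 (adjusted p = 0.0582 to 0.149), nor Ghrh without medial replicate 2 or 3 or lateral replicate 1 or 3 (0.0564 to 0.0799). The neuropeptide list had a camera adjusted p of 4.32e-07, and 0.111 with an estimated correlation. Of 23 pan-neuronal genes, 1 was lower medially, Rbfox3, at 20.4 ± 3.26 against 35.9 ± 2.14 FPKM (2 adjusted over the list alone), although 21 of 23 differences were negative. Rbfox3 did not pass when ventricular replicate 1 or any medial or lateral library was left out (adjusted p = 0.057 to 0.154). The list's camera adjusted p was 1.49e-06, and 0.307 with an estimated correlation. Among lateral markers 2 were lower and 2 higher (7 and 2 adjusted over the list alone), and the camera adjusted p was 0.0269, or 0.303 with an estimated correlation. The higher ones, Lhx6 and Lhx8, are transcription factors that also stand in the GABAergic list, and Lhx8 did not pass without medial replicate 2 (adjusted p = 0.0506). The lateral list did not pass without lateral replicate 2 (0.113).

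The erythroid list was higher medially, with 6 of 10 genes (7 adjusted over the list alone; camera adjusted p = 5.06e-07, and 0.111 with an estimated correlation). The microglia list was lower, with 0 of 11 genes passing (0 adjusted over the list alone; camera adjusted p = 5.5e-05, and 0.209 with an estimated correlation). Immediate early and stress genes had a negative median (-0.80) and a camera adjusted p of 0.0249, or 0.497 with an estimated correlation, while the 1 gene past the threshold, Btg2, was higher (1 adjusted over the list alone). That list did not pass without medial replicate 3 (adjusted p = 0.215) or lateral replicate 2 (0.178). The other 10 lists did not pass. Their adjusted p was 0.743 for the cilium, 0.547 for glutamatergic genes, 0.816 for axon guidance, 0.547 for endothelium, 0.193 for pericytes and 0.222 for meninges. It was 0.124 for oligodendrocyte precursors, 0.542 for cranial ganglia, 0.193 for telencephalon and thalamus and 0.61 for hypoxia and glycolysis. Pericytes passed without medial replicate 3 (adjusted p = 0.0406), and telencephalon and thalamus without lateral replicate 3 (0.0388). The axon guidance list had a median of -0.08 and a mean of 0.22, and the cilium list a median of 0.02 with a camera direction of down.

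In 40.4% of genes the libraries did not overlap, against 10% by chance. The count of 577 was 1760 without ventricular zone replicate 3, which enters only the shared estimate of spread, and 889 without ventricular zone replicate 2. It was 293, 222 and 294 without medial replicates 1, 2 and 3, and 240, 207 and 295 without lateral replicates 1, 2 and 3. It was 2027 with only these zones in the fit.

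Between the ventricular and medial mantle zones, no gene passed the threshold in limma, and the gene closest to it was Dlx1 (adjusted p = 0.0624). Dlx1, a transcription factor of GABAergic neurons, was 94.8 ± 11.2 FPKM in the ventricular, 216 ± 17.9 in the medial and 87.2 ± 6.83 in the lateral mantle zone. At an unadjusted p under 0.05 there were 1661 genes, 518 higher and 1143 lower in the ventricular zone. Without ventricular zone replicate 2, 571 genes passed, among them Dlx1 (adjusted p = 0.0113). With array weights, which gave ventricular zone replicate 1 a weight of 3.67 and replicate 3 one of 0.108, 2761 passed, and a mixed split of the same 6 libraries gave up to 2317. The mean of ventricular zone replicate 2 over the pan-neuronal list was 5.99 on the log2(FPKM + 1) scale, against 4.61 in the other ventricular libraries and 5.94 in the medial ones. No gene passed when the 2 shallow libraries were left out.

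The GABAergic list was lower in the ventricular than in the medial mantle zone, with 15 of 16 differences negative and a median of -1.14. Over all genes 0 of its members passed, and 13 were lower adjusted over the list alone. Its camera adjusted p was 2.2e-12, and 0.0218 with an estimated correlation, and fry gave 0.00109. No other list passed with an estimated correlation or with fry. Medial hypothalamic transcription factors were lower by camera (adjusted p = 8.97e-06), with 7 lower adjusted over the list alone, and adjusted p = 0.414 with an estimated correlation. Pan-neuronal genes were lower (adjusted p = 1.88e-07, and 0.485 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone. Stmn2, a microtubule regulator of growing axons, was 166 ± 126 against 299 ± 32.2 FPKM and did not pass, but did without ventricular zone replicate 2 (adjusted p = 0.0113).

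Lists of progenitors and division were higher in the ventricular zone by camera at the preset correlation. The median was 0.70 for mitosis (adjusted p = 6.77e-08), 0.50 for G1/S (5.88e-06), 0.47 for neurogenic genes (2.92e-05) and 0.41 for radial glia (0.00529). With an estimated correlation the adjusted p was 0.595, 0.595, 0.424 and 0.595. The mitosis and G1/S means were highest in the shallow replicate 3 of each zone, at 5.50 and 5.06 in the ventricular and 4.55 and 4.18 in the medial. The zones overlapped, since ventricular replicate 2 was at 3.93 and 3.79. Adjusted over the list alone, 5 neurogenic genes were higher and 1 lower, and 0 genes of the other 3 lists passed. Vim, an intermediate filament protein of radial glia, was 779 ± 223 against 535 ± 46.6 FPKM and did not pass. The Hedgehog, Notch, Wnt and hypoxia lists were also higher (adjusted p = 0.000453, 0.000453, 0.00549 and 0.0034), with adjusted p = 0.424, 0.472, 0.424 and 0.472 with an estimated correlation. Adjusted over the list alone, 3 Hedgehog, 3 Wnt, 0 Notch and 0 hypoxia genes were higher. Endothelial genes were lower (adjusted p = 0.0138, and 0.7 with an estimated correlation), with 0 adjusted over the list alone. Radial glia genes did not pass without ventricular replicate 1 or 3 (adjusted p = 0.146 and 0.0519), Wnt genes without ventricular replicate 1 (0.0647) and endothelial genes without ventricular replicate 3 or medial replicate 1 (0.711 and 0.165).

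The other 14 lists did not pass between these zones. The adjusted p was 0.106 for centriole genes, 0.878 for the cilium, 0.596 for glutamatergic genes, 0.211 for lateral markers, 0.0599 for neuropeptides and 0.87 for axon guidance. It was 0.872 for pericytes, 0.947 for microglia, 0.87 for erythroid genes, 0.872 for meninges and 0.292 for oligodendrocyte precursors. It was 0.943 for cranial ganglia, 0.878 for telencephalon and thalamus and 0.943 for immediate early genes. Neuropeptides passed without ventricular replicate 2, medial replicate 3 or lateral replicate 3 (adjusted p = 0.0398, 0.00272 and 0.0463), centriole genes without ventricular replicate 2 or medial replicate 3 (0.0153 and 0.004), and immediate early genes without ventricular replicate 3 (0.033). The median and mean differed in sign for microglia (0.11 and -0.08), glutamatergic genes (-0.05 and 0.26), telencephalon and thalamus (-0.30 and 0.26) and cranial ganglia (0.08 and -0.14). Axon guidance, cilium, erythroid and immediate early genes had negative medians and means with a camera direction of up. In 14.7% of genes the libraries of the 2 zones did not overlap, against 10% by chance.

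**Figure D4:**
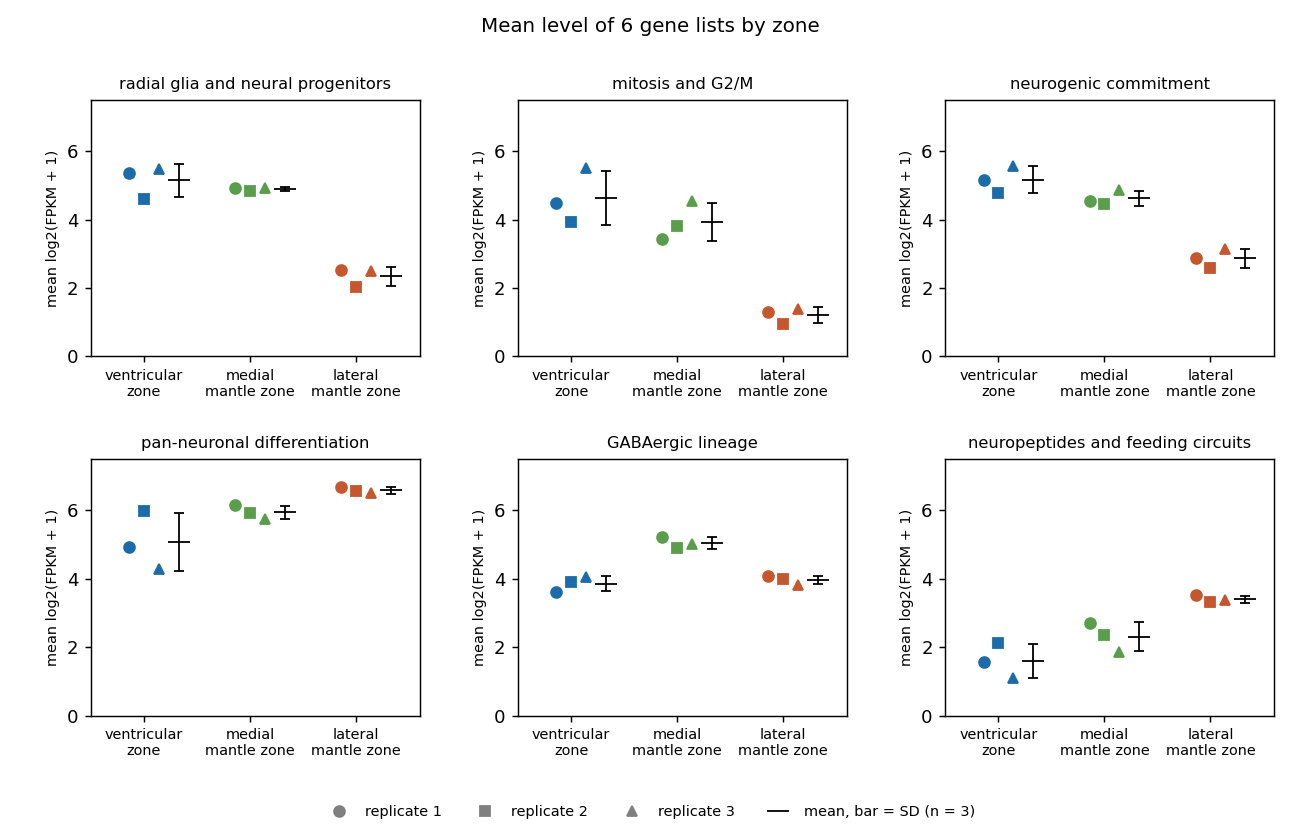
Mean log2(FPKM + 1) over the tested members (y axis) of 6 gene lists by zone (x axis); markers are libraries, and the dash with its bar is the mean and SD (n = 3). The GABAergic list is highest in the medial mantle zone (5.04 ± 0.164, against 3.86 ± 0.228 ventricular and 3.96 ± 0.128 lateral), and the mitosis list is lowest, at 1.21 ± 0.243, in the lateral mantle zone.

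Among genes differing among the 3 zones, 1504 passed by limma's F-test. Genes enriched in a zone, meaning higher than in each of the others, numbered 67 for the lateral mantle zone and 0 for the ventricular and medial mantle zones. Both counts of 0 were fixed by the 0 genes past the threshold between those zones, since enrichment in either needs a call there. They do not show that these zones lack regional genes. If the underlying calls were independent, 4.97 would have been enriched laterally. Both underlying comparisons share the lateral libraries, so part of the excess over 4.97 may come from them. Simulations without effects gave 0, but few calls arise in either comparison without effects, so that 0 sets no baseline for the overlap. Avp was the most enriched. Mab21l1, a developmental gene on chromosome 3 from 55782510 to 55785001, was 12, 10.4 and 8.60 FPKM laterally and at most 1.01 elsewhere. Nts, for neurotensin, was 5.35, 8.89 and 3.55 FPKM laterally and at most 0.539 elsewhere. Grm5, a glutamate receptor, was 6.97, 16.9 and 6.84 FPKM laterally and at most 1.34 elsewhere, and did not pass against the medial zone without medial replicate 2 (adjusted p = 0.0519).

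Cwc22, a splicing factor on chromosome 2 from 77881159 to 77946375, was 166 ± 36.5 FPKM in the lateral mantle zone, 25 ± 15.9 in the ventricular and 30.4 ± 13.5 in the medial. 6 predicted genes at 83955693 to 83993045 of the same chromosome were enriched with it. Their transcripts matched Cwc22 over 96.9% of aligned bases, so reads can be shared among them and their values are uncertain. Against the medial zone Cwc22 did not pass without lateral replicate 2 or 3 (adjusted p = 0.0715 and 0.0522). Without 1 library, the 1504 became 369 to 2894 and the 67 became 13 to 232. Each left-out library moved the 67 by over 1.5 times: it was 43, 171 and 232 without ventricular replicates 1, 2 and 3. It was 21, 13 and 25 without medial replicates 1, 2 and 3, and 15, 17 and 17 without lateral replicates 1, 2 and 3. Without ventricular zone replicate 2, 90 genes were enriched in the ventricular and 7 in the medial mantle zone. The 1504 was 624 and 2894 without ventricular replicates 1 and 2, 930 and 864 without medial replicates 1 and 2, and 369, 438 and 486 without lateral replicates 1, 2 and 3.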

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

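Leaving out the 2 shallow libraries was chosen after the data were seen. No named gene or list past the threshold changed direction under the alternatives run, but 1 of the 2750 genes called between the ventricular and lateral mantle zones had the opposite sign with quantile normalization. Among results that passed neither before nor after, 47 values of lists and 86 of named genes changed sign and were counted as the same. Over named genes, 288 values no longer passed and 147 newly passed. Over lists, the numbers were 32 and 30. The cause was not tested in any of these cases, except that leaving out libraries leaves fewer samples.

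Genes past the threshold between the ventricular and medial mantle zones numbered 0 to 571 without 1 library, 4 with a mean of at least 5 FPKM, 9 with quantile normalization and 2761 with array weights. For the ventricular against the lateral mantle zone the range without 1 library was 959 to 3958. The count was 6800 with array weights and 1684 with only the 2 zones compared. For the medial against the lateral mantle zone the range was 207 to 1760, with 3700 for array weights, 2027 with only the 2 zones compared and 1666 without the shallow libraries. Genes differing among the 3 zones ranged from 369 to 2894, with 900 without a filter, 6689 with array weights and 2870 without the shallow libraries. Genes enriched in the lateral mantle zone ranged from 13 to 232. They numbered 19 with a pseudocount of 0.1, 20 with a mean of at least 5 FPKM, 225 with quantile normalization, 417 with array weights and 207 without the shallow libraries. Ventricular enriched genes ranged from 0 to 90, with 1, 2 and 198 for the mean filter, quantile normalization and array weights. Medial ones ranged from 0 to 7, with 1, 2 and 37. Array weights were 3.67 for ventricular zone replicate 1 and 0.108 for replicate 3. With weights, a mixed split of the ventricular and lateral libraries called as many as 8623 genes, above the 6800 of the real one.

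The lists past the threshold numbered 12, 14 and 16, in the order of the comparisons above. With an estimated correlation in camera they numbered 1, 0 and 0, and with fry 1, 14 and 13. The lists that fry called were not all the same: between the ventricular and lateral mantle zones it called oligodendrocyte precursors and not microglia. Between the medial and lateral mantle zones fry called only neuropeptides lower (adjusted p = 0.00766). It did not call pan-neuronal genes, lateral markers, microglia or immediate early genes there (fry adjusted p = 0.167, 0.557, 0.0581 and 0.557), all lower by camera. Oligodendrocyte precursors were higher by fry (0.01) and did not pass by camera. Quantile normalization and trimmed mean scaling moved the median log2 difference of all genes between the medial and lateral mantle zones by -0.109 and -0.144. The share of higher calls in that comparison was 63.4% with only the 2 zones compared and 66.7% with array weights.

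With the replicate number as a block, the gene counts were 0, 2901 and 703 and the list counts 12, 15 and 17, within 1.5 times of the counts without it. With the block, immediate early genes passed between the ventricular and lateral mantle zones (camera adjusted p = 0.0333), and telencephalon and thalamus between the medial and lateral mantle zones (0.0426), and no other list changed its call. The F-test count was 1585 and the lateral enriched count 97. Same-numbered libraries had correlations of deviations from -0.098 to 0.249 (mean 0.097), with 4 of 9 over 0.1. Other pairs ran from -0.247 to 0.231 (mean -0.044), and 5 of 9 libraries correlated best with their own number. The numbers were not treated as pairs, but these values and the order of Xist over the numbers, shared by all zones, leave pairing open. Depth limits what the shallow libraries show: 1 fragment on a 2 kb gene equals 1.91 FPKM in ventricular zone replicate 3.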

Other observations

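The tests on globins, Xist and Cwc22, the fit without both shallow libraries, the nearness of ventricular zone replicate 2 to the medial ones and the position of the medial mantle zone were chosen only after the results were seen. So was the use of the counts without 1 library to weigh explanations, while those counts and the counts over other splits of the libraries were planned.

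Barhl1 was 22.2, 140 and 4.91 FPKM in the lateral libraries, and Tbr1, a transcription factor of glutamatergic neurons, was 23.8, 2.17 and 16.0. Xist, the RNA of the inactive X chromosome, was at most 0.0392 FPKM in the libraries numbered 1, 0.461 to 8.77 in those numbered 2 and 16.7 to 85.7 in those numbered 3. The Y-linked gene Eif2s3y was 25.1 to 67.8 FPKM in every library. Within each zone Xist thus rose from replicate 1 to replicate 3. These values argue against the libraries of a zone being only technical repeats of 1 RNA sample, and their mix of sexes may differ.

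In the lateral libraries the summed embryonic globins differed from the other 6 by -3.00 on the log2 scale, adult alpha globin by -1.74 (exact permutation p = 0.0119 for both, the smallest that 84 splits can give) and adult beta globin by -0.57 (exact permutation p = 0.0952). Less blood would lower them alike, so the ratio of embryonic to adult beta globin (-2.43), which is the pattern itself, argues against it as the whole cause, while less blood as part of the cause stays open. A single factor per library cancels in such a ratio, so scaling of that kind cannot have made the difference. Quantile normalization, which is not a single factor, left it at -2.57. A candidate explanation is that the lateral libraries came from other embryos, by litter or by age. The smallest gap between a lateral library and the others of its number was 0.892 on the log2 scale. That gap restates the low lateral ratio and decides nothing, since a zone effect would give it too. Cwc22, whose copy number may vary in outbred mice, was higher laterally by 2.71, which would go with other embryos but also with a zone effect. The order of Xist over the numbers was shared by all 3 zones (0.0278 by chance), which points the other way, but its lateral level was below the ventricular and medial ones in replicate 2 (0.461 against 4.17 and 8.77 FPKM) and replicate 3 (16.7 against 44.5 and 85.7), so zone and embryo cannot be told apart, because the labels name no embryo.

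The count of 0 genes between the ventricular and medial mantle zones was the other pattern followed up. No gene passed without both shallow libraries. In simulated values with each library's own noise that fit recovered 9.05% and 53.4% of genes changed by 1 and 2 on the log2 scale. With all libraries these shares were 22.5% and 67.4%. Each gene's simulated noise was taken from all 9 libraries, the shallow ones included, so the real loss of power may differ. In the data, calls rose without both, from 2750 to 3933 for the ventricular against the lateral mantle zone. For the medial against the lateral mantle zone they rose from 577 to 1666. The loss of power in the present comparison is thus uncertain, and the 0 decides little. Spread from the shallow libraries is argued against as the whole cause, since 571 genes passed with both kept but without ventricular zone replicate 2. Of these, 99 were higher and 472 lower in the ventricular zone, then held by replicate 1 and the shallow replicate 3. False calls in that fit were not simulated, so the share of the 571 that is real is not known. Ventricular zone replicate 2 may lie close to the medial libraries. Its Pearson correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.970 and 0.967 with medial replicates 1 and 2. It was 0.950 with ventricular replicate 1. Its GABAergic mean (3.92), though, was near the other ventricular ones (3.83) and not the medial ones (5.04). A single share of ventricular tissue in the medial pieces would place all progenitor genes at the same position between the lateral (0) and ventricular (1) zones. The median position was 0.67 for radial glia and 0.54 for mitosis genes, a difference of 0.13 (95% bootstrap interval over genes -0.063 to 0.187; -0.079 to 0.215 without 1 library), so this stays open. A biological overlap between the zones also stays open and was not tested.

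Other splits of the libraries were counted for each result. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For genes, 1 split, the real one, reached the 2750 of the ventricular against the lateral mantle zone, and the highest other gave 2. For the medial against the lateral mantle zone 1 split reached 577, and the highest other gave 3. For the ventricular against the medial mantle zone all 10 reached 0, as any split must, and the highest other gave 10. For lists, 2 splits reached the real 12 between the ventricular and medial mantle zones (highest other 12), 4 reached 14 between the ventricular and lateral mantle zones (highest other 16), and 2 reached 16 between the medial and lateral mantle zones (highest other 16). In each comparison a mixed split thus called at least as many lists by camera at the preset correlation as the real one. The number of lists called does not set the real zones apart. Of 100 drawn splits into 3 groups, 1, the real one, reached the 1504 genes of the F-test (highest other 932). For the 67 lateral enriched genes 4 reached the count, the real one and others with 73, 70 and 70. Both shares are under 0.05, but they take the libraries as exchangeable, which the labels do not establish. They do not tell zone from embryo. For the 0 genes enriched in the ventricular and in the medial mantle zone, all 100 reached the count (highest other 73), but any split gives at least 0, so this says nothing about chance.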
